A study of Homo sapiens with 15 samples.

How the data were processed

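SNB19 glioblastoma cells grown in DMEM with serum were transduced with lentiviral vectors, and 15 libraries in 5 groups of 3 were read (empty vector, full-length ZBTB18, its mutant, a short form and the mutant of that form). Per the labels, total RNA was extracted with Trizol, mRNA was purified on oligo-dT beads, and libraries were made with Oxford Nanopore's PCR barcoding and cDNA-PCR kits. Such reads are long, come from PCR-amplified cDNA and carry no molecular identifiers here, so amplification favouring short or GC-rich cDNA can alter a gene's share, and floors cover counting error only. The authors deposited whole-number counts per gene symbol, not normalised, with a build of GRCh38 per the submitters' processing notes. The aligner, the counting tool, its use of strand and the annotation are not given in the sources used here. Tested on the values, 145 of 6574 genes with over 100 counts in at least 8 libraries had counts that all shared a divisor between 2 and 6. Counting a read more than once would give such values, but the reason is not known. The table had 18485 symbols, of which 17975 (97.2%) matched the GENCODE annotation of GRCh38 that gave positions, lengths and GC content. Genes encoded by mitochondrial DNA and cytosolic ribosomal proteins were not analysed here: of 13 and 46 such symbols fixed beforehand, 0 and 1 were among the genes read and 0 were tested. Each CPM is thus a share of a total that hardly holds these transcripts.

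Groups and replicate numbers were taken from the sample titles. Barcode names repeat for SF-mut with an added suffix, and a second sample sheet lists SF-mut together with SF-Nte. The short-form libraries may thus have been handled apart from the others, which coincides with the form and cannot be separated from it. The suffix marks SF-mut alone, so SF-mut may also have been handled apart from SF-Nte. This limit holds for SF-mut against EV, SF-mut against SF-Nte and the interaction. Replicates of a group differed by more than sampling noise in all 5 groups (chi-square per gene from 4.23 to 38.0), so none was treated as the same library deposited again; this does not show that the replicates were separate cultures. Total counts ranged from 315693 to 1930245 per library. Over 2938 genes, the deviations of same-number libraries from their group means had correlations of 0.37, 0.14 and 0.48 between EV and FL, all over the limit of 0.1, so the numbers were taken to pair these groups. The pairing comes from the data, as the labels do not say what a number marks. Some libraries of different numbers also passed 0.1, up to 0.41 between EV replicate 1 and SF-mut replicate 2, so the limit alone does not establish pairing. In none of the other 6 comparisons of groups did all 3 pairs exceed 0.1. Among the 4 groups of the interaction they did for FL and SF-mut (0.15, 0.16 and 0.33) but for no other 2 groups, so the interaction was not taken as paired. The limit was fixed beforehand, but it was applied to single pairs of groups after the blocked fits had been run.

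Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 6767 and removed 11718, libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 15 libraries with robust dispersion (10 residual degrees of freedom). The 7 contrasts and the interaction were tested with Benjamini-Hochberg adjustment at 0.05. Levels are CPM scaled by TMM, computed from the deposited counts, and are given as mean ± SD of 3 libraries. The standard error of a log2 fold change was computed as its size divided by the square root of the F statistic. A gene with 0 counts in a group was given a bound from 3 counts over the group's libraries, and its fitted fold change is not quoted. For lists that passed in the 7 comparisons of groups, setting such members to their bound moved a list median by 0 at most; the interaction was not checked.

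Fixed before the data were examined were the design, the alternatives, 24 gene lists and the rule for the genes named: ZBTB18; the 8 highest and 8 lowest fold changes among genes past the threshold with no overlap between groups and at least 10 counts in each library of the higher group; up to 4 members per list past the threshold, or the 2 of lowest p, as values, where only the list test passed; and the 3 of lowest p in each direction where no gene passed. Levels of such genes are also given in other groups. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list moves one way without comparing it with other genes. With fewer than 5 tested members, 5 lists were not tested: mitochondrial mRNA, ribosomal proteins, and markers of immune, epithelial and endothelial cells. The summed levels of the markers of the other cell types reached at most 18.8 CPM (immune), 76.8 CPM (epithelial) and 19.7 CPM (endothelial) as a group mean. The 19 tested lists covered cholesterol synthesis under SREBP2, fatty acid synthesis under SREBP1, mesenchymal genes, extracellular matrix, proneural and neuronal genes, ID genes and BMP response, the CtBP and LSD1 corepressor complex, S phase, G2 and M phase, p53 targets, interferon response, MHC class I, NF-kB and cytokines, hypoxia and glycolysis, unfolded protein response and ATF4, YAP and TGF-beta targets, nuclear oxidative phosphorylation, and heat shock and immediate early genes. Some members of these lists were not analysed here, among them ICAM1, PTGS2, FOS, JUN and OLIG2.

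The steps were tested on simulated data: negative binomial counts with the means, library sizes and dispersions of the 6767 genes and 200 genes changed in 1 group. For FL against EV, 60.9% of the 8-fold, 19.7% of the 4-fold and 1.59% of the 2-fold changes were recovered, with 6 false calls. For FL-mut against EV, SF-mut against SF-Nte, SF-Nte against FL and the interaction, 50.8%, 51.6%, 42.4% and 13.1% of the 8-fold changes were recovered. Low counts of calls therefore do not exclude changes of 8-fold or less.

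The alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, no filter, a filter of 10 counts in 3 libraries, ZBTB18 left out, the replicate number as a block, each library left out, only the groups compared, and SF-mut left out of the fit. After seeing the data, a GC and length correction, division of counts by the common divisor, removal of 3 GC-rich libraries and thinning to the smallest total were added; for FL against EV all but the division were repeated with the replicate block, which was 1 effect per number over all 5 groups. Comparisons sharing EV were set against 40 simulated sets of unchanged groups.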

Results

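The transcriptome of SNB19 cells, a human glioblastoma cell line, was measured after lentiviral transduction with an empty vector (EV) or with 1 of 4 constructs of ZBTB18, a zinc finger transcriptional repressor. The constructs, as named in the labels, were the full-length protein (FL), a mutant of it (FL-mut), a short form (SF-Nte) and a mutant of that short form (SF-mut). The labels do not say which residues the mutations change. Each of the 5 groups had 3 replicate libraries, 15 in all. Polyadenylated RNA was read as cDNA on the Oxford Nanopore platform, and 18485 genes were counted. Total counts lay between 1274474 and 1930245 in the EV libraries, 803316 and 1393060 in FL, 865997 and 1313573 in FL-mut, 432611 and 603155 in SF-Nte, and 315693 and 597414 in SF-mut. The short-form libraries were thus shallower than the others, and 6767 genes were deep enough to be tested. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries.

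ZBTB18 itself (chromosome 1, 244048939 to 244057476, GRCh38) was low in the EV libraries and high in all 12 others. Its level was 6.17 ± 1.55 CPM (TMM-scaled counts; SD, n = 3) in EV, from 4.37 to 7.12. It reached 1442 ± 1408 CPM in FL (SD, n = 3), 3522 ± 3040 in FL-mut, 301.2 ± 147 in SF-Nte and 1793 ± 1592 in SF-mut. The lowest library of any construct group held 199 CPM, in SF-Nte. The log2 fold change against EV was 7.83 ± 1.01 (SE) for FL, 9.12 ± 1.06 for FL-mut, 5.58 ± 0.94 for SF-Nte and 8.15 ± 1.02 for SF-mut, with edgeR adjusted p = 0.0013, 0.0017, 0.049 and 0.0046. The SF-Nte value passed only narrowly and missed the threshold without any 1 of the 3 EV libraries or without SF-Nte replicate 1 or 3 (adjusted p up to 0.278). The counts cannot tell the cell's own ZBTB18 transcript from that of the vector. No pair of construct groups that was compared passed the test for ZBTB18 when adjusted over all genes tested, although the means lay far apart. The log2 difference was 1.29 ± 0.73 between FL-mut and FL (adjusted p = 0.50), 2.57 ± 0.77 between SF-mut and SF-Nte (0.57) and -2.26 ± 0.76 between SF-Nte and FL (0.19). As ZBTB18 was fixed beforehand, its unadjusted edgeR p also applies, at 0.099, 0.0044 and 0.0094 in that order. Libraries did not overlap between SF-mut (853 to 3631 CPM) and SF-Nte (199 to 470), nor between SF-Nte and FL (623 to 3067). The log2 differences became 0.34 without FL-mut replicate 3, 1.53 without SF-mut replicate 2 and -1.08 without FL replicate 2. In the other direction, FL-mut against FL reached 2.47 without FL replicate 2. Without SF-Nte replicate 1, SF-mut against SF-Nte reached 2.93 and SF-Nte against FL -2.69.

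**Figure D1:**
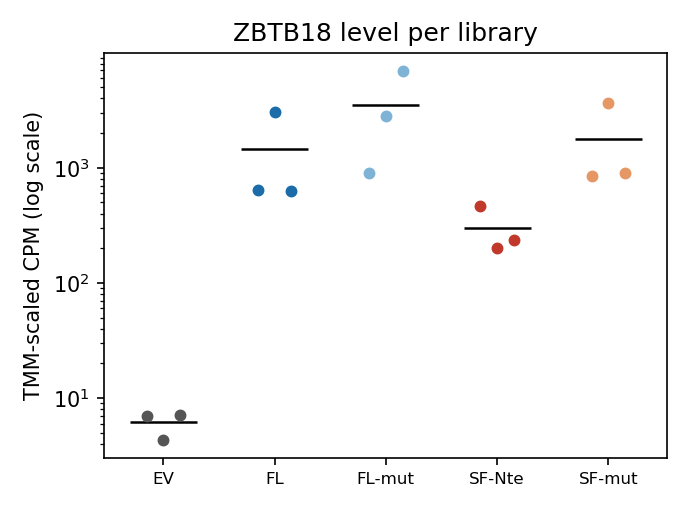
ZBTB18 level in each of the 15 libraries, in TMM-scaled CPM on a log axis, by group; points are libraries and bars are group means. The 3 EV libraries lie between 4.37 and 7.12 CPM and every construct library lies at 199 CPM or more.

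What full-length ZBTB18 changed in these cells was read from FL against EV. Transcripts of 3 S100 proteins, galectin-1 and annexin A2 fell. S100A6, a calcium-binding protein with an abundant transcript in this line, fell from 13204 ± 517 CPM in EV to 1416 ± 449 in FL (SD, n = 3 each), a log2 fold change of -3.22 ± 0.24 (SE). Its neighbours on chromosome 1, S100A4 (log2 fold change -4.44 ± 0.53, or -5.31 without FL replicate 3) and S100A2 (-4.15 ± 0.63), fell with it, as did LGALS1, which encodes galectin-1 (-3.80 ± 0.46), and HMGN3, a nucleosome-binding protein (-3.17 ± 0.29). Cancer-testis genes of the SPANX family on chromosome X rose. The calls of annexin A2 and of each SPANX gene held in at most 2 of 6 fits with 1 library left out. In these fits the log2 change of annexin A2 was as small as 0.94 in size (edgeR adjusted p up to 0.21). The list of cholesterol synthesis genes was higher as a group by the list test at a preset correlation, but had p = 0.12 with an estimated correlation.

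In FL, 21 of the 6767 genes passed an edgeR adjusted p of 0.05, 10 higher and 11 lower, against 517 genes at an unadjusted p under 0.05. Among the other lower genes were the chemokine CCL2 (82.5, 227 and 1550 CPM in the 3 EV libraries against 20.04 ± 12.9 in FL, log2 fold change -4.90 ± 0.90, adjusted p = 0.028, but -2.92 and 0.0997 without EV replicate 3, and -5.52 without FL replicate 1), the actin-associated LIM protein CSRP1 (-4.40 ± 0.80, adjusted p = 0.028, or -5.33 without FL replicate 1), the transcription factor FOXJ3 (-4.03 ± 0.72, adjusted p = 0.028) and ANXA2, annexin A2 (-1.34 ± 0.26, adjusted p = 0.046). FOXJ3 stood at 913, 94.0 and 708 CPM in the 3 EV libraries, and its call held in 2 of 6 fits with 1 library left out. Among the lower genes S100A6 had the lowest adjusted p, 3.1e-06, followed by HMGN3 (3.1e-05), S100A4 (0.00073), LGALS1 (0.00077) and S100A2 (0.0084). Besides ZBTB18, the higher genes included SPANXB1 (12.9 ± 4.26 CPM in EV, 152 ± 76.5 in FL, log2 fold change 3.53 ± 0.62), SPANXC (3.33 ± 0.61), SPANXD (2.76 ± 0.52) and the pair SPANXA1 and SPANXA2 (2.81 ± 0.56 for both), with adjusted p between 0.028 and 0.046. These SPANX genes are near-identical copies, and SPANXA1 and SPANXA2 had the same mean CPM, 155 in FL, so how many members rose is uncertain. ACYP2, an acylphosphatase (3.27 ± 0.51, adjusted p = 0.0088), and ABHD12B (3.72 ± 0.72, adjusted p = 0.041, but 2.61 and 0.31 without FL replicate 2, which held 226 CPM against 43.0 and 58.1) were also higher. With the replicate number as a block, CCL2 (-4.52 ± 0.93, adjusted p = 0.054) and ABHD12B (3.67 ± 0.75, 0.054) missed the threshold.

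Of the 25 tested members of the mesenchymal list, 4 were lower in FL and 0 higher over all genes tested, and 11 lower and 2 higher when adjusted over the list alone. Its median log2 fold change was -1.07 and its camera adjusted p was 3.1e-10, or p = 0.0069 with an estimated correlation. The extracellular matrix list had 13 of 16 members below 0 (median -0.96; adjusted p = 3.9e-05, and p = 0.048 with an estimated correlation, or 0.052 with the replicate block as well). No member passed over all genes, and 4 were lower and 1 higher adjusted over the list alone; COL5A1, a collagen chain whose deposited counts were all even, stood at 7.001, 27.7 and 105 CPM in the 3 EV libraries and 0.645 ± 1.12 in FL, and MMP2, a matrix metalloproteinase, at 33.2 ± 11.2 and 2.03 ± 2.08. The list of NF-kB and inflammatory cytokine genes had 5 of 6 members below 0 (median -2.34; adjusted p = 7.5e-05, and p = 0.013 with an estimated correlation); CCL2 was the 1 member that passed over all genes, and 4 were lower adjusted over the list alone. The cholesterol synthesis list had 18 of 21 members above 0, with a median of 1.38 and a camera adjusted p of 1.7e-08, but adjusted p = 0.12 with an estimated correlation. No member passed over all genes and 6 were higher adjusted over the list alone; INSIG1, a sterol-regulated brake on SREBP processing, stood at 9.46 ± 5.35 CPM in EV and 106 ± 65.5 in FL, and FDFT1, squalene synthase, at 265 ± 41.5 and 903 ± 473.

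The lists of YAP and TGF-beta targets (median -1.02, 9 of 11 below 0) and of proneural and glial progenitor genes (median -1.04, 5 of 6 below 0) also passed camera in FL (adjusted p = 0.0016 and 0.033), and both had p = 0.15 with an estimated correlation. Neither had a member past the threshold over all genes, and adjusted over the list alone 1 was higher and 3 lower in the former and 2 lower in the latter. Within the YAP list, CTGF, a canonical target, stood higher in FL (89.2 ± 45.0 CPM against 11.1 ± 5.80 in EV), and TPM4 lower (11.6 ± 3.14 against 55.0 ± 11.5). The proneural call was lost with the replicate block (adjusted p = 0.059) and without EV replicate 3, FL replicate 1 or FL replicate 2 (up to 0.196). The other 13 lists did not pass (adjusted p from 0.13 to 0.91).

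The gene count was 6 (1 higher and 5 lower) without EV replicate 3 or FL replicate 2, 9 (2 and 7) without EV replicate 2, 13 (6 and 7) without FL replicate 3 and 14 (1 and 13) without EV replicate 1, whereas ZBTB18, S100A6, S100A4, S100A2, LGALS1 and HMGN3 passed in all 6 such fits. DESeq2 called 140 genes, and a GC and length correction in a fit with the replicate block gave 8 higher and 13 lower. Groups did not overlap for 16.9% of genes, where chance gives 10%.

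**Figure D2:**
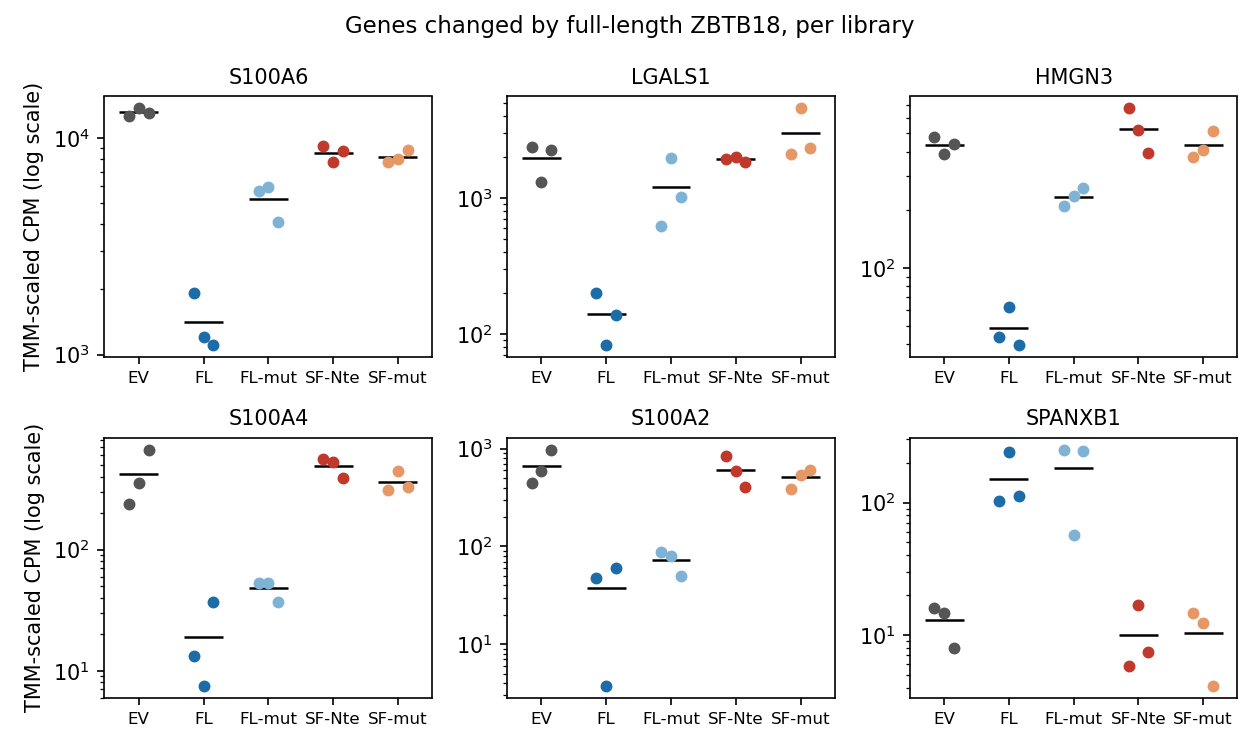
Levels of 6 genes in each of the 15 libraries, in TMM-scaled CPM on log axes, by group; points are libraries and bars are group means. S100A6 (mean 1416 CPM), LGALS1 (141 CPM) and HMGN3 (48.5 CPM) are lowest in the FL libraries, S100A4 and S100A2 are low in both full-length groups, and SPANXB1 is high in both.

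FL-mut against EV asked what the mutated full-length construct still changed. SPANX genes rose here too, with SPANXB1 at 184 ± 110 CPM (log2 fold change 3.81 ± 0.63, SE, n = 3) and SPANXC, SPANXA1, SPANXA2 and SPANXD between 3.18 and 3.79, or between 2.55 and 2.96 without FL-mut replicate 1. S100A4 (-3.14 ± 0.49), S100A2 (-3.22 ± 0.60), CCL2 (-4.75 ± 0.90, but -2.81 with adjusted p = 0.17 without EV replicate 3, and -5.50 without FL-mut replicate 2) and FOXJ3 (-4.22 ± 0.73) fell. S100A6 also fell, to 5263 ± 1012 CPM, a log2 change of -1.33 ± 0.22. ZMYM3, a zinc finger protein of histone-modifying complexes, had 0 counts in the 3 FL-mut libraries against 24.0 ± 14.8 CPM in EV, at least 25.8-fold lower if 3 counts over the group are taken as the floor. PGRMC1, a haem-binding membrane protein, fell from 2643 ± 1607 to 105 ± 63.9 CPM (-4.65 ± 0.89, but -4.07 with adjusted p = 0.15 without EV replicate 2, which held 4491 CPM).

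In all, 13 genes passed for FL-mut, 6 higher and 7 lower (709 at an unadjusted p under 0.05), with edgeR adjusted p from 0.0017 for ZBTB18 to 0.046 for PGRMC1. The cholesterol synthesis list had 20 of 21 members above 0, a median of 1.19 and a camera adjusted p of 1.2e-05, and the mesenchymal list a median of -0.59 with 2 of 25 members lower (0.0053). Both had adjusted p = 0.37 with an estimated correlation. Adjusted over the list alone, 3 members were higher in the former, and 6 were lower in the latter. Within the former, DHCR7, the last reductase of the pathway, stood at 43.9 ± 19.6 CPM in FL-mut and 5.57 ± 1.33 in EV. The extracellular matrix list (median -0.62, 13 of 16 below 0, adjusted p = 0.039) and the nuclear oxidative phosphorylation list (median -0.24, 24 of 35 below 0, adjusted p = 0.014) passed with no member called over all genes, and they too had adjusted p = 0.37 with an estimated correlation. Adjusted over the list alone, 1 and 2 members were lower. The other 15 lists did not pass (adjusted p from 0.14 to 0.97). The extracellular matrix call was lost without EV replicate 3, FL-mut replicate 1 or FL-mut replicate 3 (adjusted p up to 0.253), and the oxidative phosphorylation call without EV replicate 3 or FL-mut replicate 1 (up to 0.126).

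Of the 13 genes, ZBTB18 alone passed with each of the 6 libraries left out in turn; the count was 1 without EV replicate 3, FL-mut replicate 1 or FL-mut replicate 3, 5 without EV replicate 2 and 28 without EV replicate 1. DESeq2 called 145 genes, and DESeq2 size factors in edgeR gave 6 higher and 4 lower.

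How the mutation altered the effect of the full-length protein was tested directly in FL-mut against FL. Of the genes lower in FL than in EV, a comparison that shares the FL libraries, 3 stood higher with the mutant than with FL. S100A6 was 1.89 ± 0.23 higher on the log2 scale (SE, n = 3) in FL-mut than in FL, HMGN3 2.28 ± 0.28 and LGALS1 3.08 ± 0.45. S100A16, another S100 gene of the chromosome 1 cluster, was 3.27 ± 0.56 higher in FL-mut (3.97 without FL replicate 1) and had not passed between FL and EV (43.03 ± 29.7 against 259 ± 113 CPM), although it did with the replicate block (-2.65 ± 0.45, adjusted p = 0.026). LGALS1 stood at 141 ± 59.3 CPM in FL, 1199 ± 696 in FL-mut and 1978 ± 590 in EV, and HMGN3 at 48.5 ± 12.01, 235 ± 24.9 and 438 ± 46.3. ZMYM3 was at least 22.8-fold lower in FL-mut (0 counts, against 21.2 ± 8.69 CPM in FL), and SLC35D2, a nucleotide sugar transporter, was lower by a log2 change of -2.66 ± 0.44. The SPANX genes, S100A4, S100A2, CCL2 and FOXJ3, which changed against EV in both groups, were not among the genes called between FL-mut and FL.

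These 6 genes, 4 higher and 2 lower, were all that passed (821 at an unadjusted p under 0.05), with edgeR adjusted p of 0.0019 for S100A6 and HMGN3, 0.0096 for LGALS1, 0.030 for S100A16, 0.020 for ZMYM3 and 0.025 for SLC35D2. The mesenchymal list was higher in FL-mut (median 0.35, 15 of 25 above 0, 2 past the threshold; adjusted p = 0.013, and p = 0.17 with an estimated correlation), and so was the hypoxia and glycolysis list (median 0.26, 15 of 18 above 0; adjusted p = 0.016, and p = 0.17 with an estimated correlation), in which PKM, pyruvate kinase, stood at 9424 ± 1679 CPM against 3410 ± 1645 in FL. The nuclear oxidative phosphorylation list was lower (median -0.50, 27 of 35 below 0; adjusted p = 0.00071, and p = 0.17 with an estimated correlation); COX7C, a small subunit of cytochrome oxidase, stood at 1488 ± 56.3 CPM against 2931 ± 329. The mean of that list's fold changes was 0.01, of the opposite sign to its median and test. Adjusted over the list alone, 5 mesenchymal members were higher and 1 lower, 4 hypoxia members were higher, and 2 oxidative phosphorylation members were higher and 11 lower. The other 16 lists did not pass (adjusted p from 0.058 to 0.68).

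S100A6 and HMGN3 passed in all 6 fits with 1 library left out, and the count was 2 without FL replicate 3, 3 without FL replicate 2 and 3 without FL-mut replicate 3. DESeq2 called 116 genes, while a fit of these 6 libraries alone called 0. The mesenchymal and hypoxia calls were each lost without FL replicate 2 or FL-mut replicate 1 (adjusted p up to 0.114 and 0.0644).

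The short form was compared with EV in the same way. In SF-Nte cells ZBTB18 was higher and SQSTM1 and MRNIP were lower, and no other gene passed. SQSTM1, which encodes the autophagy receptor p62, stood at 2460 ± 2310 CPM in EV and 150 ± 28.6 in SF-Nte (log2 fold change -4.03 ± 0.59, SE, n = 3; edgeR adjusted p = 0.029), and MRNIP at 1241 ± 1113 and 102 ± 18.5 (-3.60 ± 0.57; 0.038). Without EV replicate 2, which held 5102 CPM of SQSTM1 against 1457 and 822 in the other EV libraries, the log2 fold changes were -2.94 (adjusted p = 0.028) and -2.58 (0.074). The pair overlap on chromosome 5, SQSTM1 spanning 179806398 to 179838078 on the plus strand and MRNIP 179835133 to 179862173 on the minus strand, so their counts may not be independent measurements. S100A6, LGALS1, HMGN3, S100A4 and S100A2, all lower in FL, did not pass in SF-Nte. Their levels there were 8564 ± 769, 1917 ± 69.3, 530 ± 140, 495 ± 89.2 and 611 ± 217 CPM. The EV means were, in the same order, 13204, 1978, 438, 421 and 672 CPM. For S100A6 all SF-Nte libraries (7727 to 9240 CPM) lay below all EV libraries (12727 to 13753 CPM). As 1.61% of simulated 2-fold changes were recovered in this contrast, a missing call does not show an unaltered level.

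The SF-Nte count of 3 genes compares with 489 at an unadjusted p under 0.05 and 31 by DESeq2. Of 19 lists, hypoxia and glycolysis passed (median 0.36, 10 of 18 above 0, 1 higher adjusted over the list alone; camera adjusted p = 0.041, and p = 0.19 with an estimated correlation); PGK1, a glycolytic kinase, stood at 1422 ± 67.4 CPM against 674 ± 245. The other 18 lists did not pass (adjusted p from 0.13 to 0.94), including cholesterol synthesis, with 11 of 21 members above 0 and a median of 0.04. Over all genes the median log2 fold change was -0.13 and became 0.08 with a GC and length correction.

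None of the 3 calls held in all 6 fits with 1 library left out; the count was 0 without SF-Nte replicate 1 or replicate 3 and 1 without EV replicate 2, and the hypoxia call was lost without EV replicate 2 or SF-Nte replicate 1 or 2 (adjusted p up to 0.198). With DESeq2 size factors 0 genes were higher and 1 lower, and limma-voom and the GC and length correction called 0.

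In SF-mut cells 4 genes passed against EV. ZBTB18 was higher, and PGRMC1 fell from 2643 ± 1607 to 31.5 ± 20.8 CPM (log2 fold change -6.33 ± 0.99, SE, n = 3; edgeR adjusted p = 0.022), or by -5.78 without EV replicate 2 (adjusted p = 0.037) and -7.17 without SF-mut replicate 1 (0.062). It stood at 306 ± 123 CPM in FL and 239 ± 295 in SF-Nte and did not pass there (adjusted p = 0.16 and 0.30). SQSTM1 (210 ± 44.7 CPM, -3.55 ± 0.57, adjusted p = 0.025) and MRNIP (98.4 ± 17.9 CPM, -3.66 ± 0.57, adjusted p = 0.022) were lower here as well, by -2.52 and -2.70 without EV replicate 2 (adjusted p = 0.036 and 0.031). The hypoxia and glycolysis list was higher (median 0.39, 15 of 18 above 0, 1 higher adjusted over the list alone; camera adjusted p = 0.012, and p = 0.10 with an estimated correlation). BNIP3, a mitophagy receptor induced by low oxygen, stood at 146 ± 199 CPM against 9.21 ± 2.52, with most of the SF-mut counts in replicate 2. The other 18 lists did not pass (adjusted p from 0.44 to 0.91).

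For SF-mut, 363 genes had an unadjusted p under 0.05 and DESeq2 called 26, and the edgeR count was 1, ZBTB18, without any 1 of the 3 SF-mut libraries. The hypoxia call was lost without EV replicate 2 or SF-mut replicate 2 (adjusted p up to 0.148), and without the 3 GC-rich libraries (EV replicate 1, FL-mut replicate 2 and SF-mut replicate 2) 0 genes and 0 lists passed.

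**Figure D3:**
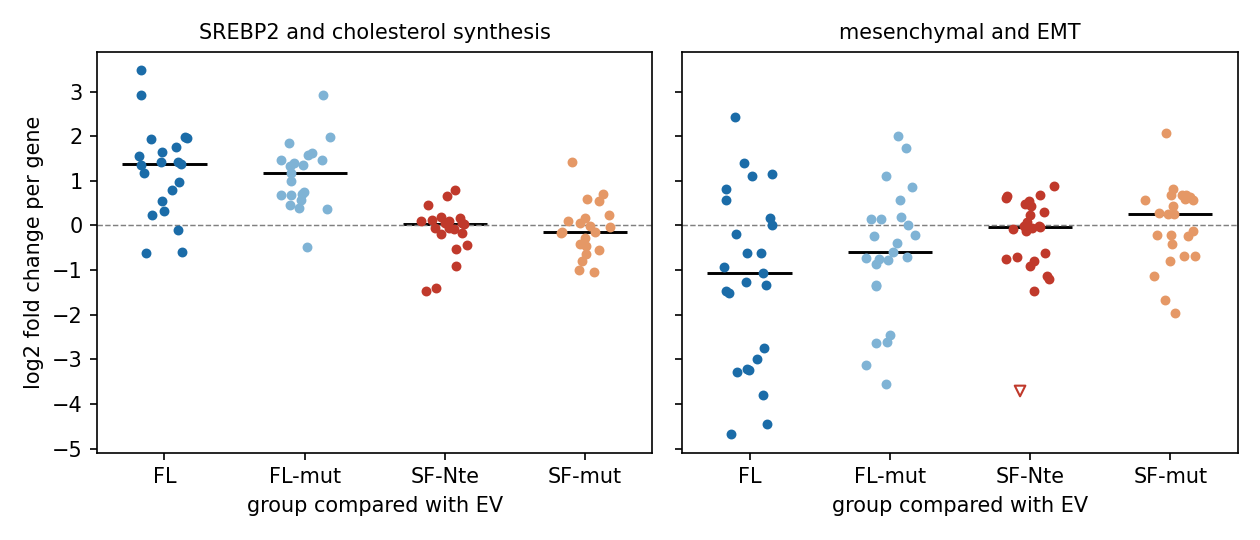
Log2 fold changes against EV of the 21 tested genes of the cholesterol synthesis list and the 25 of the mesenchymal list, for each construct; points are genes, bars are medians of the fitted values, and the open triangle is the bound for TAGLN, at 0 counts in SF-Nte. The cholesterol list has medians of 1.38 in FL, 1.19 in FL-mut, 0.04 in SF-Nte and -0.15 in SF-mut.

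SF-mut against SF-Nte asked whether the mutation altered the effect of the short form. No gene passed in edgeR (0 higher, 0 lower; 564 genes at an unadjusted p under 0.05), while DESeq2 called 4. The genes with the lowest p were, on the higher side, HCCS, a haem lyase (0 counts in SF-Nte, 12.2 ± 2.28 CPM in SF-mut, SD, n = 3), TRIP10, a membrane-curving adaptor (0 counts in SF-Nte and 17.97, 92.5 and 24.6 CPM in the SF-mut libraries), and DNAJC2, a ribosome-associated chaperone (2.08 ± 1.91 and 28.8 ± 12.4 CPM). On the lower side they were CDIPT (16.5 ± 9.77 CPM in SF-Nte, 0 counts in SF-mut), ABCB6 (10.5 ± 4.08 CPM and 0 counts) and SLC27A5 (43.3 ± 17.4 and 9.56 ± 4.27 CPM). All 6 had adjusted p = 0.57. S100A6 stood at 8211 ± 559 CPM in SF-mut and HMGN3 at 433 ± 70.5, close to the SF-Nte levels given above.

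The nuclear oxidative phosphorylation list was lower in SF-mut than in SF-Nte (median -0.40, 24 of 35 below 0, none called over all genes or adjusted over the list alone; camera adjusted p = 0.0068, and p = 0.95 with an estimated correlation). Its mean was 0.11, again of the other sign. ATP5G2, an ATP synthase subunit, stood at 2022 ± 394 CPM against 3354 ± 459, whereas COX5B stood at 396 ± 645 against 30.3 ± 6.86, and its log2 difference of 3.68 turned to -0.35 without SF-mut replicate 2. The list call was lost without SF-mut replicate 1 (adjusted p = 0.054). The other 18 lists did not pass (adjusted p from 0.52 to 0.94).

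The contrast between the unmutated forms, SF-Nte against FL, gave the most calls in the main fit. This did not hold with limma-voom, where FL against EV had 14 higher and 13 lower, or without the filter. Among the genes higher in SF-Nte were some that had been lower in FL than in EV, a comparison that shares the FL libraries: CCL2 (687 ± 89.1 CPM against 20.04 ± 12.9; log2 difference 5.05 ± 0.91, SE, n = 3), S100A4 (4.68 ± 0.53), CSRP1 (4.23 ± 0.81), S100A2 (4.01 ± 0.63), LGALS1 (3.76 ± 0.46), S100A6 (2.60 ± 0.23) and ANXA2 (32937 ± 2978 CPM against 8128 ± 641; 2.02 ± 0.27). FOXJ3, also lower in FL than in EV, did not pass here (154 ± 93.5 CPM in SF-Nte against 34.6 ± 13.4 in FL, adjusted p = 0.17). In SF-mut it stood at 34.8 ± 15.4 CPM, near its FL level, though it did not pass between SF-mut and EV. SELENBP1, a selenium-binding protein (3.77 ± 0.75), SH3BGRL (3.61 ± 0.59), PLEKHG1 (3.63 ± 0.77) and the transcription factor MYC (2.73 ± 0.62) were also higher in SF-Nte. In CPM, the EV, FL and SF-Nte means were 61.7, 8.44 and 116 for SELENBP1 and 74.0, 11.9 and 144 for SH3BGRL. They were 12.5, 2.35 and 29.6 for PLEKHG1 and 48.8, 9.96 and 66.3 for MYC. The EV means thus lay between those of FL and SF-Nte, so part of each difference may lie in a lower FL level. Without FL replicate 1 the log2 differences were 5.65 for CCL2 and 5.15 for CSRP1. Without FL replicate 3 they were 5.53 for S100A4 and 4.24 for PLEKHG1 (adjusted p = 0.057). Several genes had 0 counts in the SF-Nte libraries: with 3 counts over the group as the floor, TAGLN, a smooth muscle actin-binding protein, was at least 34.9-fold lower than in FL (72.1 ± 16.3 CPM), the growth factor MDK at least 20.8-fold (42.9 ± 13.3 CPM), the ubiquitin ligase SYVN1 at least 16.1-fold (33.2 ± 12.6 CPM), the transcription factor TCF3 at least 8.91-fold (18.4 ± 9.23 CPM) and HCCS at least 6.85-fold (14.2 ± 6.13 CPM). CTGF was lower too, by a log2 difference of -4.43 ± 0.98. In SF-mut, MDK and TCF3 also had 0 counts, while TAGLN stood at 5.99 ± 10.4 CPM, SYVN1 at 3.42 ± 5.92 and HCCS at 12.2 ± 2.28. An effect of the form cannot be told apart here from separate handling of the short-form libraries, nor from the amount of ZBTB18 transcript. That amount was 199 to 470 CPM in the SF-Nte libraries and 623 to 3067 in FL, without overlap.

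In this contrast 72 genes passed, 33 higher and 39 lower in SF-Nte (891 at an unadjusted p under 0.05), with edgeR adjusted p of 2.3e-05 for S100A6, 0.00043 for S100A4, 0.00088 for LGALS1, 0.0020 for ANXA2, 0.014 for CCL2, 0.044 for MYC and 0.040 for CTGF. SLC44A3-AS1, annotated as a transcribed pseudogene, and 2 genes without a given symbol, AC275455.1 and AC079597.3, were among the lowest and are not described. The mesenchymal list was higher in SF-Nte, with 6 of 25 members higher and 1, TAGLN, lower (9 and 1 adjusted over the list alone; median 0.57; camera adjusted p = 3.4e-09, and p = 0.010 with an estimated correlation). The hypoxia and glycolysis list was higher as well (median 0.50, 14 of 18 above 0, 4 higher adjusted over the list alone; adjusted p = 0.00047, and p = 0.028 with an estimated correlation), with PGK1 at 1422 ± 67.4 CPM against 592 ± 92.5.

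The cholesterol synthesis list was lower in SF-Nte than in FL (median -1.24, 20 of 21 below 0, 3 lower adjusted over the list alone; adjusted p = 8.5e-05, and p = 0.19 with an estimated correlation), HMGCS1, which makes HMG-CoA, standing at 8.02 ± 3.32 CPM against 91.1 ± 50.4. Higher in SF-Nte at the preset correlation were the lists of extracellular matrix (median 0.66, 11 of 16 above 0, adjusted p = 0.0012), NF-kB and cytokine (1.93, 4 of 6, 0.0057), YAP and TGF-beta (1.03, 9 of 11, 0.0012), proneural and glial progenitor (1.06, 3 of 6, 0.016) and neuronal differentiation genes (0.87, 4 of 6, 0.034). With an estimated correlation these 5 had adjusted p of 0.093, 0.060, 0.11, 0.11 and 0.11. Adjusted over the list alone they had 5, 2, 2, 3 and 1 members higher, and the YAP list 1 lower. Over all genes, CCL2 passed in the NF-kB list, and TPM4 (higher, 2.12 ± 0.47, adjusted p = 0.040) and CTGF (lower) in the YAP list. PDGFRA, a receptor of glial progenitors, had 0 counts in FL and 12.9 ± 9.03 CPM in SF-Nte, at least 14.1-fold more by the group mean. It did not pass (edgeR adjusted p = 0.10), and the SF-Nte libraries held 9, 10 and 1 counts of it. The other 11 lists did not pass (adjusted p from 0.063 to 0.94).

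Of the 72 genes, 9 passed in all 6 fits with 1 library left out, among them ANXA2, HMGN3, LGALS1, S100A2, S100A4, S100A6 and SH3BGRL; the count was 12 without FL replicate 2 (10 higher and 2 lower) or SF-Nte replicate 3 (9 and 3), 13 without SF-Nte replicate 1 (12 and 1) and 21 without SF-Nte replicate 2 (14 and 7), so that most lower calls were lost in these fits. MYC, PLEKHG1, TPM4 and CTGF passed in 0 of these 6 fits (edgeR adjusted p up to 0.19). SELENBP1, SYVN1 and TCF3 passed in 1, CCL2, TAGLN, MDK and HCCS in 2 and CSRP1 in 3. The neuronal call was lost in each of the 6 fits, the proneural call without FL replicate 2 or SF-Nte replicate 1 (adjusted p up to 0.0651) and the NF-kB call without FL replicate 3 (0.0821). DESeq2 called 296 genes (127 higher and 169 lower) and limma-voom 24 (22 and 2), a GC and length correction gave 56 higher and 37 lower, and the median over all genes moved from -0.15 to 0.04 with it.

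Whether the mutation acted differently in the short and the full-length form was tested as an interaction, the SF-mut minus SF-Nte difference against the FL-mut minus FL difference. HMGN3 and S100A6 passed. Both were higher in FL-mut than in FL, and neither passed between SF-mut and SF-Nte, where no gene did. The difference of differences was -2.57 ± 0.39 (log2, SE, n = 3 per group) for HMGN3 and -1.95 ± 0.31 for S100A6, with edgeR adjusted p of 0.039 and 0.043. HMGN3 stood at 530 ± 140 CPM in SF-Nte and 433 ± 70.5 in SF-mut, and S100A6 at 8564 ± 769 and 8211 ± 559. The mesenchymal list (median -0.46, 17 of 25 below 0, 1 lower over all genes and 1 higher and 2 lower adjusted over the list alone) and the NF-kB and cytokine list (median -1.29, 6 of 6 below 0, none past either adjustment) had a camera adjusted p of 0.048 each, and p = 0.32 and 0.24 with an estimated correlation. CCL2 in the latter stood at 233 ± 75.9 CPM in SF-mut and 687 ± 89.1 in SF-Nte. The other 17 lists did not pass (adjusted p from 0.053 to 0.87).

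In the interaction, 315 genes had an unadjusted p under 0.05 and DESeq2 called 8. The count of 2 became 1 without FL replicate 1 or 2 or SF-Nte replicate 3 and 0 without any other 1 of the 12 libraries. The NF-kB call was lost in 6 of the 12 fits with 1 library left out and the mesenchymal call in 3, without FL replicate 2, FL-mut replicate 2 or SF-Nte replicate 2.

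The comparisons with EV share its 3 libraries. FL and FL-mut had 11 calls in common, 6 higher and 5 lower: ZBTB18, the 5 SPANX genes, S100A6, S100A4, S100A2, CCL2 and FOXJ3. Lists of this length drawn independently would share 0.00887 higher and 0.0114 lower genes, a value that leaves out the shared EV libraries. In 40 simulated sets of unchanged groups no comparison had over 1 call, so their shared count of 0 decides nothing at this threshold. Across genes, which are not independent replicates, the fold changes of FL and FL-mut had r = 0.41 and a covariance of 0.415, against a simulated mean r of 0.49 and covariance of 0.294, a covariance difference of 0.121. FL and SF-Nte had 1 call in common, ZBTB18 (expected 0.00148 higher and 0.00325 lower), with r = 0.17 and a covariance of 0.188 against a simulated 0.46 and 0.294. SF-Nte and SF-mut shared ZBTB18, SQSTM1 and MRNIP, 3 calls (expected 0.000148 higher and 0.000887 lower), with r = 0.24 and a covariance of 0.274 against 0.43 and 0.293. The simulated groups were drawn independently, whereas EV and FL libraries of one number varied together, which by itself lowers such a covariance, so the simulated values are not exact where FL is included. Part of any excess may come from the shared EV libraries, which are too few to split.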

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

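The tests of GC and length, of shared reads, of separate handling and of other splits were chosen after the results they bear on had been seen; the tests of ZBTB18 amount and of depth were set before their outcome was seen. Groups of 3 libraries are too small for a test of single outlying libraries. What drew attention were the items whose response to the mutation differed between the forms in the interaction: HMGN3, with a log2 difference of -2.57, S100A6, with -1.95, the mesenchymal list, with a median of -0.46, and the NF-kB and cytokine list, with -1.29. Redrawing mutant and unmutated labels within each form gave 2 or more genes in 1 of 100 splits, the real one. The others gave at most 1 gene. Redrawn groups mix FL with FL-mut libraries, which differed in both genes, and this widens the spread within them. Few calls would be expected in such splits in any case, so the test cannot decide whether the 2 calls arose by chance. Both list calls were lost with an estimated correlation.

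The first pattern is that S100A6, LGALS1, HMGN3 and S100A16 stood higher in FL-mut than in FL. The first 3 of them were lower in FL than in EV, a comparison that shares the FL libraries. A lower amount of ZBTB18 transcript in FL-mut was not seen. Its mean level was higher there, although the difference did not pass (log2 difference 1.29, edgeR adjusted p = 0.50). With log2 ZBTB18 CPM as a covariate over the 12 construct libraries, the median log2 difference of the 4 genes was 2.49, against 2.66 without it. S100A6 (adjusted p = 0.015) and HMGN3 (0.024) stayed past the threshold, while the call of LGALS1 ended, its log2 difference going from 3.05 (adjusted p = 0.020) to 2.86 ± 0.53 (SE; 0.12), and S100A16 missed the threshold in this 12-library fit both without the covariate (3.25, adjusted p = 0.053) and with it (3.04 ± 0.61, 0.18). A GC and length correction left a median of 2.48 and 3 of the 4 calls; S100A6 went from 1.89 ± 0.23 to 1.58 ± 0.33 (adjusted p = 0.094), its call ending with a smaller fold and a larger error. The ZBTB18 covariate had 1 slope for all 4 construct groups, and in the short-form groups the 4 genes stood above FL. That fit therefore cannot exclude an effect of ZBTB18 amount. Why these transcripts differed between FL-mut and FL stays open, as protein amounts were not measured.

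The second pattern is the spread between libraries of one group: 1 component held 39.7% of the within-group variance of 2938 genes, with EV replicate 1, FL-mut replicate 2 and SF-mut replicate 2 at one end. GC content and length explained 20.7% of its gene loadings, just past the 20% set for this explanation, so a bias in amplification or reading may contribute, and SF-mut replicate 2 showed the steepest GC trend (0.51 log2 units per 10 points of GC). The correction removed 9.33% of the within-group variance, so most of the component remains unaccounted for. Depth is open: the component had r = -0.39 (permutation p = 0.35) and rho = -0.29 (permutation p = 0.43) with total count over 15 libraries, and r = -0.15 without the 2 libraries farthest from the median. As the spread lies within groups, no biological explanation was tested.

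The third pattern is that SQSTM1 and MRNIP were lower in both short-form groups than in EV. Their annotated spans overlap by 2946 bases, and the SD of their log2 count ratio over 15 libraries was 0.22 against 1.69 for SQSTM1 itself, consistent with reads shared between the overlapping genes, so that the pair may be 1 change. This leaves open why the pair was lower. Separate handling of the short-form libraries cannot be told apart from an effect of the form, because both coincide; 72 genes passed between the 6 short-form and the 9 other libraries, 34 higher and 38 lower.

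With 10 splits of 6 libraries into 3 and 3, no comparison of 2 groups can give a share under 0.05. The real split gave 21 genes for FL against EV (highest other 0), 13 for FL-mut against EV (1), 3 for SF-Nte against EV (0), 4 for SF-mut against EV (1), 6 for FL-mut against FL (1) and 72 for SF-Nte against FL (0), the real split being the 1 with as many genes in each. For FL and EV, taken as paired by replicate number, the 3 other splits that part all 3 pairs gave 0, as did the 6 that part 1 pair. For SF-mut against SF-Nte all 10 splits gave 0. The other splits mix libraries of the 2 groups, which widens the spread within them where the groups differ. Few calls would be expected in such splits in any case, so these counts cannot decide whether the calls arose by chance.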

How the results depend on the processing

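The GC and length correction, the common divisor, the removal of 3 GC-rich libraries and the thinning were chosen after seeing the data, and so were their repeats with the replicate block. Of 2601 values for single genes under an alternative, 2088 kept their direction and side of the threshold, 425 no longer passed, 86 newly passed and 2 turned: COX5B in SF-mut against SF-Nte, to -0.35 without SF-mut replicate 2 (up to 4.12 with another library left out) and to -0.36 without the GC-rich libraries, because 1 library held most of its counts. Of 394 counts of genes or lists and ZBTB18 values, 256 kept their side or stayed within 1.5 times, 123 moved further and 15 no longer passed. Without the filter 18485 genes were tested and 202, 219, 121, 81, 348, 193, 301 and 49 genes passed for FL against EV, FL-mut against EV, SF-Nte against EV, SF-mut against EV, FL-mut against FL, SF-mut against SF-Nte, SF-Nte against FL and the interaction, where 21, 13, 3, 4, 6, 0, 72 and 2 had passed. In the same order DESeq2 called 140, 145, 31, 26, 116, 4, 296 and 8. A fit of only the groups compared gave 13, 3, 1, 2 and 0 for the first 5 and 130 for SF-Nte against FL; the filter was applied anew there, leaving 6499, 6527, 5057, 5330, 5824 and 4432 genes. Limma-voom gave 20 for FL-mut, 0 for SF-Nte and 0 for SF-mut against EV and 24 for SF-Nte against FL. SF-Nte against EV had 1 gene with DESeq2 size factors, 0 with the GC and length correction and 0 with SF-mut left out of the fit. Without the 3 GC-rich libraries, 35, 21 and 0 genes passed for FL, FL-mut and SF-mut against EV, 119 for SF-Nte against FL and 0 in the interaction, which had 1 with the GC and length correction. The cause was not tested where none is named. With 1 library left out the counts ran from 6 to 29 (FL against EV), 1 to 28 (FL-mut), 0 to 4 (SF-Nte), 1 to 5 (SF-mut), 2 to 8 (FL-mut against FL), 12 to 64 (SF-Nte against FL) and 0 to 1 (interaction).

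Of lists, 6, 4, 1, 1, 3, 1, 8 and 2 passed in that order of comparisons. With an estimated correlation 3, 0, 0, 0, 0, 0, 2 and 0 passed. With fry, 3 passed for FL against EV, 4 for FL-mut against FL, 8 for SF-Nte against FL and 0 for FL-mut, SF-Nte and SF-mut against EV, SF-mut against SF-Nte and the interaction. Without the filter, 5 passed for FL-mut against FL, 4 for SF-mut and 2 for SF-Nte against EV and 5 for SF-Nte against FL. In a fit of only the groups compared, 2 passed for FL-mut and 2 for SF-Nte against EV, and 2 for SF-Nte with SF-mut left out. The interaction had 0 with DESeq2 size factors, 0 with the GC and length correction and 1 after thinning. SF-Nte against EV had 0 with the common divisor and 0 after thinning. Without the GC-rich libraries, 5 passed for FL-mut against FL and 0 for SF-mut against EV. With 1 library left out the number of lists ran from 2 to 5 (FL-mut against EV), 2 to 7 (FL-mut against FL), 0 to 6 (interaction), 0 to 3 (SF-mut against EV), 0 to 2 (SF-mut against SF-Nte) and 0 to 4 (SF-Nte against EV).

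ZBTB18 kept its direction under every alternative run. Its log2 fold change for SF-Nte against EV no longer passed with DESeq2 size factors (5.58), limma-voom (5.46), SF-mut left out (5.56), the common divisor (5.58), the GC and length correction (5.73), thinning (5.55) or the GC-rich libraries left out (5.70), and ran from 5.10 to 5.76 with 1 library left out. For FL (7.32) and SF-mut (7.70) it no longer passed with limma-voom, nor for SF-mut without the GC-rich libraries (7.21). At an unadjusted p under 0.01, 69 calls were shared by FL and FL-mut, 8 by FL and SF-Nte and 26 by SF-Nte and SF-mut, where unchanged groups drawn independently against the same controls shared 8.93, 8.68 and 7.40 on average. With DESeq2 size factors the last pair of comparisons shared 1 call and FL and SF-Nte 0.

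The replicate number was also fitted as a replicate block: 25, 11, 5 and 5 genes passed for FL, FL-mut, SF-Nte and SF-mut against EV, 7 for FL-mut against FL, 0 for SF-mut against SF-Nte, 81 for SF-Nte against FL and 2 in the interaction, and 5 lists for FL-mut against FL. For FL against EV, taken as paired by number, the block ended the calls of CCL2, ABHD12B, CAV2 and HNMT. It added S100A16, PKM, PEG10, LDHB, EEF1G, SH3BGRL, MGST3 and NAA38. The block also ended the proneural list call (5 lists in place of 6) and changed no other of these calls. With an estimated correlation it left 2 lists, and with fry 6. In fits with the block, 21 genes passed with the GC and length correction, 30 after thinning and 62 without the GC-rich libraries. In the other 6 comparisons of groups the libraries share only a number, and in the interaction FL and SF-mut alone met the limit. Over all groups, 10 of 30 same-number pairs had a correlation of deviations over 0.1 (from -0.20 to 0.64), and 8 of 15 libraries matched best with a library of their own number in another group. The short-form libraries held 315693 to 603155 counts; thinned to the smallest total, 3937 genes could be tested and 64 passed for SF-Nte against FL.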

Other observations

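The genes described here were chosen after their values were seen, and so was the test. Genes of the unfolded protein response and ATF4 list, which respond to amino acid shortage and protein folding stress, varied between replicates of a group. The mean log2 CPM of its 18 tested genes was 7.11 in FL-mut replicate 2 and 4.999 in FL-mut replicate 1, and 6.50 in SF-mut replicate 2 and 4.36 in SF-mut replicate 1. In no comparison did the list pass camera.

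A hypothesis is that replicates of one number shared a culture or handling condition, such as medium age. Replicate 2 was highest in 4 of the 5 groups and replicate 1 lowest in 3. The mean deviation from the group was -0.60 for replicate 1, 0.54 for replicate 2 and 0.06 for replicate 3, and permuting the numbers within groups over all 7776 arrangements gave an exact p of 0.011 (two-sided, on the spread of the 3 means). This may reflect a shared condition for these genes, or a technical one: FL-mut replicate 2 and SF-mut replicate 2 also lay at the GC-rich end of the largest component of the spread within groups (0.371 and 0.641), and FL-mut replicate 1 and SF-mut replicate 1 towards its other end (-0.366 and -0.270). EV went against the technical account, as replicate 1 lay at the GC-rich end (0.208) but 0.27 below its group for these genes, while replicate 2 was 0.54 above it and lay at -0.010. SF-mut replicate 3 went against it as well, lying at -0.371 on the component but 0.26 above its group for these genes. The explanations were not separated. SF-Nte did not follow the pattern, and over all genes used 10 of 30 pairs of libraries with one number had deviations with a correlation over 0.1. It was found and tested on the same libraries.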
